A study of Arabidopsis thaliana with 12 samples.

How the data were processed

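Transcript levels were measured in Arabidopsis thaliana of the Landsberg erecta (Ler) ecotype on 12 oligonucleotide arrays with 2 colours. Each array carried RNA of callus after 10 days on an auxin-rich callus-inducing medium together with RNA of the explant of the same organ at day 0. The organs were root, cotyledon and petal, with 4 arrays each from biologically independent samples. Per the labels, callus RNA carried Cy5 in replicates 1 and 3 and Cy3 in replicates 2 and 4, and the RNA was amplified with T7 polymerase before the dyes were coupled. The group of every array was taken from its label, and no 2 arrays held identical values.

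The authors deposited 1 table of log2 ratios, with 24926 of 26090 oligonucleotide probes holding a value. The scanner, image software, background correction, normalization and filters behind these log2 ratios are not given in the sources used here, and scanner intensities were not analysed here. The unit was read from the values, which lay on both sides of 0 and stopped at 6.64 and -6.64, the log2 of a 100-fold ratio, with 578 values at a further floor of -33.22. Of 299112 values, 13.9% were at a limit (tolerance 1e-04 around it), 9280 at the upper and 32441 at the lower limit including the floor. Such a value bounds a ratio and does not measure it, so it was treated as missing. Signal over background, which sets the precision of a ratio, was not analysed here, and the 4 arrays per tissue limit the precision of every value.

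The direction of the ratios is not stated. Arrays of opposite dye within a tissue correlated positively across the 16799 probes measured on all 12 arrays, with r from 0.80 to 0.86 in root, 0.86 to 0.91 in cotyledon and 0.84 to 0.91 in petal, so the deposited ratios had already been turned to 1 direction. Over all values, limits included, these correlations ran from -0.59 to -0.25 in root, -0.09 to 0.43 in cotyledon and 0.31 to 0.91 in petal, because values at a limit followed the dye in root and partly in cotyledon. In root, 1168 probes were at the upper limit on both arrays with callus in Cy5 and at the lower limit on both arrays with callus in Cy3, against 30 in cotyledon and 0 in petal. The rule set before the data were examined spoke of all probes. Leaving limited values out of it was decided after the data were seen, and the ratios were used as deposited. Callus over explant is the likely direction, since the labels give callus as channel 1 and the day-0 tissue as control, and since most tested GH3 and IAA genes lay above 0 and most photosynthesis genes below 0 after culture on auxin. Exceptions were IAA29 in cotyledon (-0.85), GH3.17 in petal (-0.71) and LHCB4.3 in cotyledon (0.25). The signs of these lists are therefore not independent evidence of the direction, and a table stored the other way round would turn every sign together.

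Medians of the deposited values, limits included, were 0.45, -0.37, 0.26 and -0.04 for root replicates 1 to 4, -0.30, -0.35, 0.29 and -0.32 for cotyledon replicates 1 to 4, and -0.74, -0.64, -0.16 and -0.14 for petal replicates 1 to 4. Medians of measured ratios alone lay between -0.28 and 0.22. How the authors centred and scaled the arrays stays unknown, and no further normalization was applied.

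Probes were named from the platform's probe table, in which 13960 probes had 1 gene, 0 had several and 12130 had none. Locus tags were matched to the RefSeq gene table of assembly TAIR10.1 for symbols, with 13912 of the named probes matched and 48 not. No coordinates are given because the build behind the probes is not given in the sources used here. A probe was kept if it was measured on at least 3 of the 4 arrays of every tissue. This left 18169 probes, of which 9886 had a gene. They gave 9695 genes, 187 of them as the mean of several probes. In 0 of these 187 did probe means lie more than 0.5 from 0 in opposite directions in a tissue. A symbol other than a locus code was at hand for 1189 tested genes. Control spots were left out.

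The log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per tissue and a dye term per gene, over all 12 arrays. Each coefficient was tested against 0 (2-sided), and differences between tissues were tested as contrasts of the same fit. P-values were adjusted by Benjamini-Hochberg over the 9695 genes, and genes with an adjusted p under 0.05 count as changed. The dye term passed this threshold in 351 genes. Values are given as the fitted log2 ratio ± SD over the arrays that measured the gene. On simulated ratios for 9695 genes, of which 200 were changed in root alone, 31.3% of changes of 0.5 on the log2 scale, 76.1% of changes of 1 and 93.9% of changes of 2 were recovered in root, and 11 of 145 calls were false. The same 3 sizes gave 20.9%, 82.1% and 93.9% with 0 of 131 calls false in cotyledon, and 26.9%, 82.1% and 93.9% with 8 of 143 calls false in petal. For the difference between cotyledon and root, with the change planted in root, 8.96%, 52.2% and 90.9% were recovered. Far fewer genes changed in these simulations than were called in the data, so the shares need not carry over.

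Before the data were examined, 21 gene lists with 379 genes were fixed, of which 37 genes were tested here. Lists with at least 3 tested members were root meristem regulators (5 of 23), auxin response and transport (5 of 23), cell cycle and DNA replication (4 of 44), photosynthesis (12 of 64) and ribosome and nucleolus (3 of 19). They were tested with camera (limma) at a preset correlation of 0.01 against all tested genes, with adjustment over 15 tests for the tissues and 15 for the differences. On simulated root ratios, 15 of 200 unchanged lists of 12 genes had p under 0.05. Genes were simulated as independent, whereas the correlation estimated within the tested lists ran from 0.225 to 0.803. This share therefore need not hold for them. Both camera with an estimated correlation and fry were run on the 8974 genes measured on all 12 arrays. Lateral root initiation (1 of 18), cytokinin response (1 of 17), floral organ identity and petal (1 of 16), lateral organ polarity and leaf growth (2 of 18), root hair and root epidermis (2 of 13) and wound and jasmonate (1 of 13) had too few members for a list test. Stomatal lineage, shoot epidermis and cuticle, anther and pollen, shoot meristem regulators, endodermis and suberin, root nutrient uptake and loading, vascular tissue, flavonoid and anthocyanin synthesis, embryo and seed, and low-oxygen response had 0 tested members and are not analysed here. List genes carry the symbol used in the list, which for ACR4, ARR16, MCM7, LHCB1.5, RCH1, RPL27AC and RPL28A differs from that in the gene table.

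Genes named in the text follow a rule set before the data were examined. It took, per tissue, the 6 highest and 6 lowest ratios among changed genes with a symbol and the same sign on all 4 arrays. It added up to 2 higher and 2 lower members of each list with the lowest adjusted p, and the 6 genes highest and 6 lowest in all 3 tissues by their smallest absolute ratio. Per difference between tissues it took the 4 highest and 4 lowest, and 12 fixed genes where measured. Of these 12, LBD16 was tested, and WOX5, PLT1, PLT2, SCR, SHR, LBD29, WUS, CUC2, CYCB1;1, LHCB1.1 and AP3 are not analysed here. Other list members are named to describe their list.

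Alternatives fixed before the data were examined were a fit with no dye term, each tissue fitted alone, the replicate number as a block in place of the dye term, arrays centred on their measured median, arrays scaled to 1 median absolute value, probes measured on all 12 arrays, no filter, every probe on its own, array weights, a robust eBayes, a size threshold of 1 on the log2 scale, both other list tests, and leaving out each array in turn. Limited ratios kept at their limits, centring on tested probes, centring on all values, and leaving out both root replicate 1 and petal replicate 1 were added after the data were seen.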

Results

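Callus formed from root, cotyledon and petal explants of Arabidopsis was compared with the explant it grew from. Callus is a mass of dividing cells, induced here by 10 days on auxin-rich medium. Each of the 12 arrays gave the ratio of 1 callus sample to 1 explant sample, with 4 arrays per organ, and 9695 genes were tested with limma. Ratios are given as callus over explant on the log2 scale, which is the likely direction and is not stated by the labels. The array numbers limit the precision, and so do ratios at the 100-fold limit, which took from 1.99% of the probes on cotyledon replicate 1 to 28.2% on petal replicate 2.

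**Figure D1:**
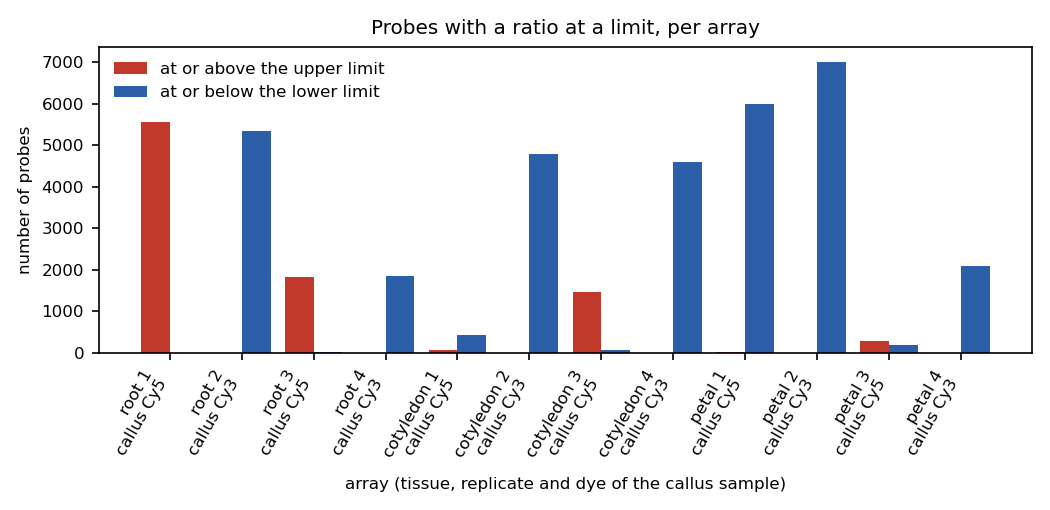
Number of probes at the upper and lower limit (bars, y axis) on each array (x axis, with the dye of the callus sample). Root replicate 1 had 5566 probes at the upper limit, and petal replicates 1 and 2 had 5996 and 7022 at the lower limit.

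The first comparison asked which transcripts change as root tissue becomes callus. SWEET1 (AT1G21460), a sugar transporter, had the highest ratio of the named genes, 3.68 ± 0.21 (SD, n = 4), or 12.8-fold. It was followed by ZW2 (AT1G58330) at 3.37 ± 0.08, and by APL4 (AT2G21590), a large subunit of the ADP-glucose pyrophosphorylase of starch synthesis, at 3.03 ± 0.19. The auxin-conjugating enzyme GH3.3 (AT2G23170) stood at 2.71 ± 0.23, ATL43 (AT5G05810) at 2.68 ± 0.25 and the AP2-type transcription factor BBM (AT5G17430) at 2.66 ± 0.24. The carboxypeptidase-like gene scpl31 (AT1G11080) had the lowest ratio of the named genes, -4.17 ± 0.49, or 18-fold lower. The next lowest of the named genes were tny (AT5G25810) at -3.69 ± 0.55, the light-harvesting gene LHCB1.5 (AT2G34420) at -3.6 ± 0.61, SP1L2 (AT1G69230) at -3.38 ± 0.32, the subtilase ATSBT5.2 (AT1G20160) at -3.19 ± 0.71 and BZIP24 (AT3G51960) at -3.16 ± 0.39. By the rule that named them, these 12 genes had the same sign on all 4 root arrays, and their limma adjusted p was 0.00044 or less. In all, 3866 genes were higher and 2226 lower in root callus, 62.8% of those tested, and 5779 of the 6092 changed genes had the same sign on all 4 arrays. The centring of the arrays moves this balance: with arrays centred on the median of tested probes, 3020 were higher and 2767 lower, so 52.2% of changed genes were higher in place of 63.5%.

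Photosynthesis genes fell in root callus. All 12 tested members were lower, with the same count when adjusted over the list alone, a median of -1.84 and a camera adjusted p of 2.05e-05 (adjusted p = 0.378 with an estimated correlation). Among them were LHCB1.5, the photosystem I subunit PSAN (AT5G64040) at -1.99 ± 0.29, the ATP synthase subunit ATPC1 (AT4G04640) at -2.27 ± 0.44 and the Rubisco activase RCA (AT2G39730) at -2.16 ± 0.32. LHCB1.5 belongs to a family of near-identical paralogs, so its signal may include its relatives. Of 5 root meristem regulators, BBM, the receptor kinase gene RCH1 (AT5G48940) at 1.70 ± 0.41 and the receptor kinase gene ACR4 (AT3G59420) at 1.57 ± 0.29 rose and UPB1 (AT2G47270) fell to -0.73 ± 0.43, while JKD (AT5G03150) was at -0.14 ± 0.21. The list as a whole did not pass (camera adjusted p = 0.312), and UPB1 lost its call without root replicate 1 (-0.51, adjusted p = 0.103), with no dye term (still -0.73, 0.0669), with arrays centred on the median of all values (-0.81, 0.0566) and without root replicate 1 and petal replicate 1 (-0.53, 0.0995), in a range from 0.00269 to 0.103 over its alternatives. In the auxin list, IAA30 (AT3G62100), an auxin-induced repressor of auxin signalling, rose to 2.64 ± 0.22, GH3.3 rose and GH3.1 (AT2G14960) rose to 1.59 ± 0.50, whereas IAA29 at 0.55 ± 0.28 and GH3.17 at 0.21 ± 0.21 did not pass, nor did the list (camera adjusted p = 0.0976). The 4 cell cycle genes rose, namely the mitotic Aurora kinases AUR1 (AT4G32830) at 0.82 ± 0.21, AUR2 (AT2G25880) at 1.1 ± 0.16 and AUR3 (AT2G45490) at 1.1 ± 0.37 (n = 3) and the replicative helicase subunit MCM7 (AT4G02060) at 1.11 ± 0.15, but the list did not pass (camera adjusted p = 0.0906). AUR3 rests on 3 root arrays, and with limited ratios kept its root value was -0.81 (adjusted p = 0.66). AUR1 and AUR2 are close paralogs. Of the ribosomal genes, RPL27AC (AT1G70600) rose to 0.73 ± 0.24, a call lost with no dye term (still 0.73, adjusted p = 0.055) and with centring on the median of all values (0.66, adjusted p = 0.0794, range 0.000218 to 0.0794), while PGY1 was at 0.43 ± 0.60 and RPL28A at 0.03 ± 0.42 (camera adjusted p = 0.653).

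Lists with 1 or 2 tested members gave single values in root callus. PHV (AT1G30490), a class III HD-ZIP factor of the upper side of lateral organs, rose to 2.04 ± 0.07, and the jasmonate-responsive defensin PDF1.2 (AT5G44420) rose to 1.98 ± 0.66. LBD16 (AT2G42430), a transcription factor that acts in lateral root initiation, was at 0.66 ± 0.82 and did not pass (adjusted p = 0.14). Without root replicate 3 it did, at 1.12 (adjusted p = 0.0216, range 0.0216 to 0.637 over its alternatives). The response regulator ARR16 (AT2G40670) at -1.23 ± 0.31 did not pass over all genes (limma adjusted p = 0.0757). It was lower when adjusted over the list alone, but with 1 tested member in the list this is its unadjusted p. YAB3 at -0.11 ± 1.60, the root hair expansins EXPA7 at -0.25 ± 0.68 and EXPA18 at 0.57 ± 0.98, and the petal gene RBE at 0.62 ± 1.88 (n = 3) did not pass either way. All other counts within lists were the same when adjusted over the list alone, in all 3 tissues.

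**Figure D2:**
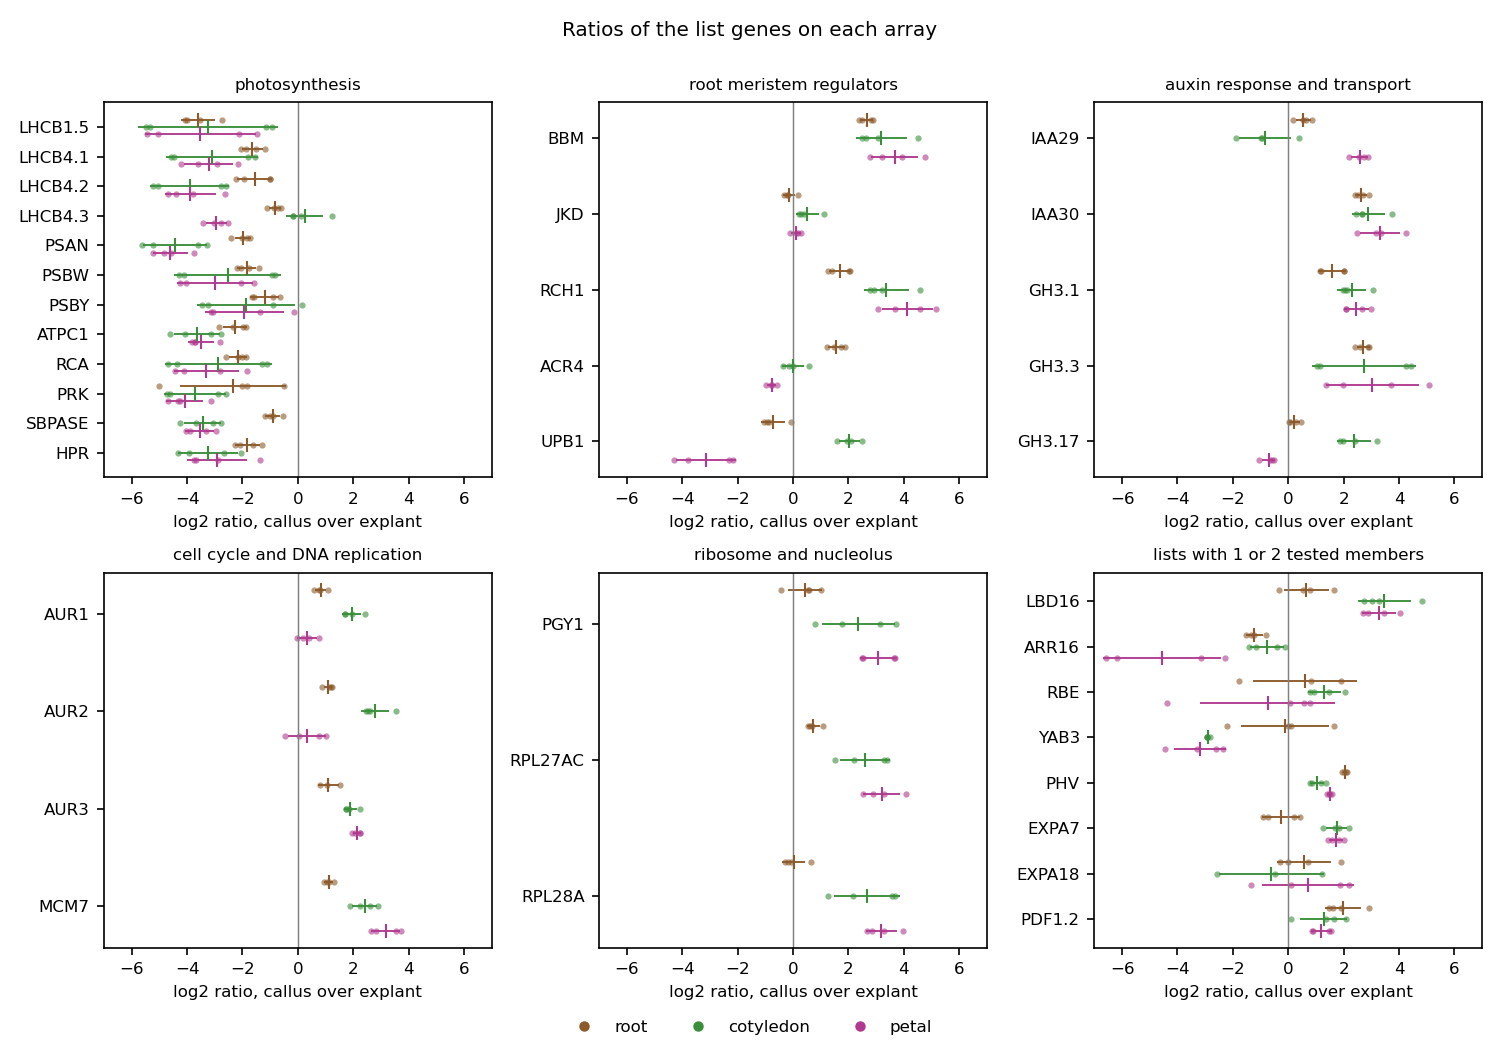
Log2 ratios of callus over explant (x axis) of the genes of the fixed lists (y axis), by tissue. Points are arrays, ticks the fitted mean and bars the SD over arrays. Fitted means of photosynthesis genes lie below 0 in all 3 tissues except LHCB4.3 in cotyledon, at 0.25.

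The cotyledon comparison asked which transcripts change as this organ becomes callus. OSM34 (AT4G11650), an osmotin-like defence protein, reached 4.28 ± 0.99 (n = 4), or 19.5-fold. The spindle checkpoint gene BUBR1 (AT2G33560) was at 4.08 ± 0.48, the expansin gene EXPA4 (AT2G39700) at 3.91 ± 0.92 and the histone H3 kinase gene Haspin (AT1G09450) at 3.90 ± 0.52. XTH20 (AT5G48070), of the xyloglucan endotransglucosylase family, stood at 3.78 ± 1.08 and PR-1-LIKE (AT2G19990) at 3.74 ± 0.47. Among the named genes with the same sign on all 4 arrays, AOP3 (AT4G03050) of glucosinolate synthesis was lowest at -4.51 ± 0.92, or 22.8-fold lower. Next came PSAN at -4.44 ± 1.17, the cytochrome P450 gene CYP71B5 (AT3G53280) at -4.34 ± 0.13 and PIFI (AT3G15840), which encodes a chloroplast protein, at -4.13 ± 0.68. The sugar transporter SWEET11 (AT3G48740) was at -4.08 ± 0.91 and CYP71B34 (AT3G26300) at -3.98 ± 0.29. Their limma adjusted p was 7.26e-06 or less, and by the naming rule their sign was the same on all 4 arrays. In all, 3948 genes were higher and 2935 lower, 71.0% of those tested, with 6570 of the 6883 on the same side on all 4 arrays. Of the changed genes 57.4% were higher, against 52% (3555 and 3282) with arrays centred on tested probes and 64.5% (3930 and 2167) with centring on the median of all values.

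In cotyledon callus 11 of 12 photosynthesis genes fell, with a median of -3.23 (camera adjusted p = 6.2e-05; adjusted p = 0.378 with an estimated correlation). The exception was LHCB4.3 (AT2G40100) at 0.25 ± 0.67, which did not pass. The Calvin cycle enzyme SBPASE (AT3G55800) fell to -3.44 ± 0.67, and LHCB1.5 ranged from -5.50 on an array with callus in Cy3 to -0.92 on an array with callus in Cy5. The 11 genes that fell were lower on both arrays with callus in Cy3 than on both with callus in Cy5, and the median of the list was -4.44 against -2.00. All 4 cell cycle genes rose, AUR2 to 2.80 ± 0.51 and MCM7 to 2.41 ± 0.44, with a median of 2.18 for the list (camera adjusted p = 0.0343; adjusted p = 0.378 with an estimated correlation). AUR1 was at 1.95 ± 0.34, and AUR3 at 1.89 ± 0.23, a call lost at an unchanged ratio with limited ratios kept (adjusted p = 0.157, range 8.92e-08 to 0.157). The list call was also lost with each tissue fitted alone (0.0617), on probes measured on all 12 arrays (0.111) and without root replicate 1 and petal replicate 1 (0.0539), in a range from 0.00938 to 0.378 over its camera alternatives. BBM at 3.18 ± 0.92, RCH1 at 3.37 ± 0.82, UPB1 at 2.04 ± 0.37 and JKD at 0.52 ± 0.41 rose among the root meristem regulators, ACR4 was at 0.01 ± 0.40, and the list did not pass (camera adjusted p = 0.0976). LBD16 rose to 3.47 ± 0.95 (limma adjusted p = 9.17e-06). IAA30 at 2.89 ± 0.59, GH3.3 at 2.73 ± 1.88, GH3.17 (AT1G28130) at 2.37 ± 0.61 and GH3.1 at 2.3 ± 0.52 rose and IAA29 (AT4G32280) fell to -0.85 ± 0.94 (list camera adjusted p = 0.114). The GH3.3 ratio followed the dye, at 4.45 and 4.26 with callus in Cy5 and 1.15 and 1.05 with callus in Cy3. IAA29 lost its call without cotyledon replicate 1 (-0.50, adjusted p = 0.126), 3 (-0.85, 0.0528) or 4 (-0.77, 0.0728), with each tissue fitted alone (-0.85, 0.0627) and with centring on the median of all values (-0.68, 0.0667), in a range from 0.000529 to 0.126. The ribosomal genes RPL28A (AT2G19730) at 2.67 ± 1.18, RPL27AC at 2.59 ± 0.90 and PGY1 (AT2G27530) at 2.36 ± 1.33 rose. Their median was 1.70 with callus in Cy3 and 3.44 with callus in Cy5. Their list did not pass (camera adjusted p = 0.0906) but did without cotyledon replicate 2 (0.036), with no filter (0.0375) and with limited ratios kept (0.0333), in a range to 0.378 over its camera alternatives. Of the smaller lists, EXPA7 (AT1G12560) at 1.75 ± 0.39, PDF1.2 at 1.29 ± 0.85 and PHV at 1.04 ± 0.27 rose and YAB3 (AT4G00180), a factor of the lower side of lateral organs, fell to -2.91 ± 0.06. RBE at 1.31 ± 0.58, ARR16 at -0.77 ± 0.62 and EXPA18 at -0.61 ± 1.90 (n = 3) did not pass.

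The petal comparison gave the widest ratios of the 3 tissues, with an SD of 1.67 across genes against 1.38 in cotyledon and 1 in root. JAL22 (AT2G39310), a jacalin-related lectin, rose to 4.59 ± 0.81 (n = 4), or 24-fold, and EXO (AT4G08950) to 4.48 ± 0.84. BUBR1 stood at 4.36 ± 0.29, sks15 (AT4G37160) at 4.36 ± 0.83, XTH20 at 4.34 ± 0.65 and Haspin at 4.31 ± 0.51. RALFL25 (AT3G25165), a gene for a RALF-like signalling peptide, fell to -5.01 ± 1.44, or 32.3-fold lower, SWEET4 (AT3G28007) to -4.78 ± 1 and CSLA01 (AT4G16590), of the cellulose synthase-like family, to -4.65 ± 1.3. PSAN was at -4.60 ± 0.62, ARR16 at -4.55 ± 2.14 and AtS40-3 (AT4G18980) at -4.55 ± 1.08. The ARR16 ratio followed the dye, at -3.15 and -2.30 with callus in Cy5 and, near the limit, -6.57 and -6.19 with callus in Cy3. By the naming rule all 12 had the same sign on the 4 petal arrays, and their limma adjusted p was 0.00144 or less. In all, 4387 genes were higher and 3235 lower, 78.6% of those tested, and 7044 of the 7622 had the same sign on all 4 arrays. With limited ratios kept at their limits, 4289 were higher and 5337 lower among 13510 genes, and with arrays centred on the median of all values 5011 were higher and 2146 lower, so the balance of directions in petal depends on how limited ratios are treated.

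All 12 photosynthesis genes fell in petal callus, with a median of -3.40 (camera adjusted p = 2.86e-05; adjusted p = 0.378 with an estimated correlation). SBPASE was at -3.55 ± 0.51, LHCB4.3 at -2.94 ± 0.37 and PSBY (AT1G67740), of photosystem II, at -1.93 ± 1.44. The size followed the dye here too, with a list median of -4.06 with callus in Cy3 and -2.82 with callus in Cy5, as against -2.03 and -1.56 in root. The root meristem regulators went both ways. RCH1 rose to 4.13 ± 0.93 and BBM to 3.67 ± 0.86, UPB1 fell to -3.14 ± 1.07 and ACR4 to -0.77 ± 0.17, and JKD was at 0.11 ± 0.17. The list did not pass, its median of 0.11 and mean of 0.80 lay above 0, and camera gave a downward shift (camera adjusted p = 0.952). LBD16 rose to 3.27 ± 0.61 (limma adjusted p = 1.05e-05). Of the auxin genes IAA30 at 3.31 ± 0.72, GH3.3 at 3.04 ± 1.69, IAA29 at 2.58 ± 0.30 and GH3.1 at 2.46 ± 0.45 rose and GH3.17 fell to -0.71 ± 0.25 (list camera adjusted p = 0.175). The GH3.3 ratio followed the dye here too, at 5.08 and 3.72 with callus in Cy5 and 1.99 and 1.37 with callus in Cy3. ACR4 and GH3.17 lost their calls with arrays centred on the median of all values (-0.35, adjusted p = 0.141, range 2.94e-05 to 0.141, and -0.29, adjusted p = 0.357, range 0.000764 to 0.357). MCM7 rose to 3.2 ± 0.53 and AUR3 to 2.13 ± 0.15, and AUR1 at 0.33 ± 0.35 and AUR2 at 0.34 ± 0.69 did not pass (list camera adjusted p = 0.175). With limited ratios kept AUR3 stayed at 2.13 in petal but lost its call (adjusted p = 0.0911, range 9.76e-08 to 0.0911), since the fit shares its spread with root, where 1 limited value entered. RPL27AC at 3.2 ± 0.66, RPL28A at 3.19 ± 0.57 and PGY1 at 3.08 ± 0.66 rose. Their list did not pass (camera adjusted p = 0.0906) but did with no filter (0.04) and with limited ratios kept (0.0333), in a range to 0.378 over its camera alternatives. EXPA7 at 1.72 ± 0.26, PHV at 1.5 ± 0.09 and PDF1.2 at 1.19 ± 0.38 rose, ARR16 and YAB3 at -3.17 ± 0.94 fell, and RBE at -0.74 ± 2.44 and EXPA18 at 0.71 ± 1.65 did not pass. None of the 5 camera calls over tissues and differences held with an estimated correlation.

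The next comparison asked which changes the 3 callus types have in common. Of the genes with a symbol that were higher in all 3, GH3.3, BBM and IAA30 had the highest minimum over the tissues. They were followed by the calmodulin-binding family gene iqd15 (AT3G49380) at 2.46 ± 0.25 in root, 2.45 ± 0.44 in cotyledon and 3.00 ± 0.55 in petal, the bZIP factor EEL (AT2G41070) at 2.37 ± 0.33, 2.55 ± 0.62 and 2.99 ± 0.90, and the thaumatin-like gene ATLP-1 (AT1G18250) at 2.35 ± 0.19, 3.23 ± 1.04 and 3.6 ± 0.60 (n = 4 each). Lower in all 3 were LHCB1.5, at -3.23 ± 2.53 in cotyledon and -3.52 ± 2.00 in petal, the autophagy gene ATG8E (AT2G45170) at -2.98 ± 0.62 in root, -2.92 ± 0.79 in cotyledon and -3.21 ± 3.2 (n = 3) in petal, and the trihelix factor GT2 (AT1G76890) at -2.75 ± 0.42, -3.95 ± 0.24 and -3.96 ± 0.19. The P450 genes CYP71B20 (AT3G26180) at -2.82 ± 0.25, -3.58 ± 0.23 and -4.44 ± 0.74, CYP71B34 at -2.71 ± 0.34 in root and -2.73 ± 0.80 (n = 3) in petal, and CYP71B29 (AT1G13100) at -2.69 ± 0.25, -3.07 ± 0.41 and -2.63 ± 0.92 (n = 3 in petal) fell as well. In all, 2231 genes were higher in the 3 tissues, against 712 for independent calls of the same numbers, and 1070 were lower, against 225. With arrays centred on tested probes the numbers were 1749 and 1422, so 55.2% of the shared genes were higher in place of 67.6%. The tissues share no samples, but each count rests on the same fit and dye term.

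Across the 9695 genes, which are not independent replicates, the responses of cotyledon and petal correlated most (Pearson's r = 0.71, Spearman's rho = 0.71), then root and petal (0.53 and 0.56) and root and cotyledon (0.44 and 0.45). Single arrays of cotyledon and petal correlated at 0.61 to 0.70, of root and petal at 0.37 to 0.57 and of root and cotyledon at 0.29 to 0.47, all under the pairs within petal (0.84 to 0.91), cotyledon (0.83 to 0.93) and root (0.73 to 0.82). With limited ratios kept at their limits, the root correlations were 0.33 with petal and 0.30 with cotyledon.

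**Figure D3:**
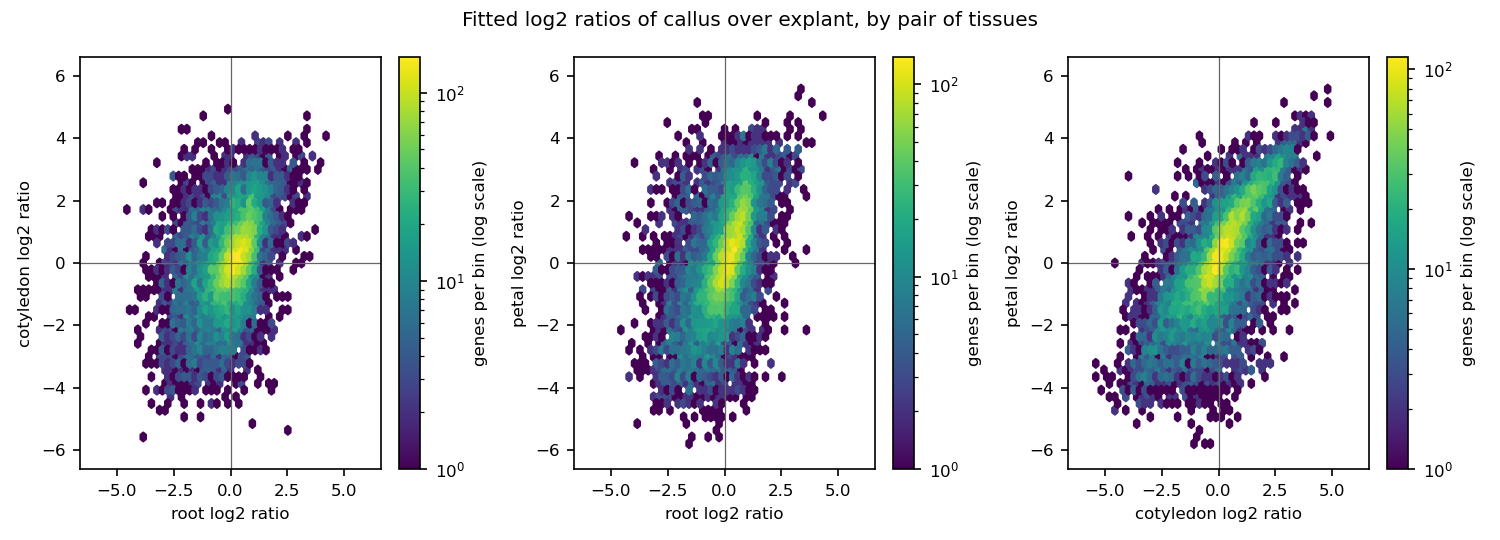
Fitted log2 ratios of callus over explant of the tested genes in 1 tissue (x axis) against another (y axis), as bins coloured by the number of genes on a log scale. The correlation is highest for cotyledon and petal (r = 0.71) and lowest for root and cotyledon (r = 0.44).

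The contrast of cotyledon with root asked where the change from explant to callus differs between the organs. Calli of different organs never shared an array, so this and both next contrasts hold differences between explants as well as between calli. Higher or lower in a contrast refers to the ratio and not to a transcript level in callus. OSM34 rose in cotyledon callus and fell in root callus to -2.10 ± 0.88. The same held for the expansin genes EXPB3 (AT4G28250), at 3.15 ± 0.70 in cotyledon and -3.14 ± 0.36 in root, and EXPA15 (AT2G03090), at 3.41 ± 0.62 and -2.16 ± 0.59, and for PRA1.B5 (AT5G01640) at 3.5 ± 0.85 and -1.76 ± 0.46. In the other direction, CYP71B5 was at 0.29 ± 0.32 in root. The calmodulin-like gene CML41 (AT3G50770) was at -2.42 ± 0.56 in cotyledon and 1.72 ± 1.01 in root, the chaperonin gene Cpn60beta4 (AT1G26230) at -2.65 ± 0.18 and 1.37 ± 0.63, and the pyruvate orthophosphate dikinase gene PPDK (AT4G15530) at -2.15 ± 0.21 and 1.77 ± 0.36. These 8 differences had a limma adjusted p of 5.19e-05 or less. LBD16 rose more in cotyledon than in root, by 2.81 (adjusted p = 0.0011), and so did the 4 cell cycle genes and the 3 ribosomal genes, each with a camera adjusted p of 0.0688 for the list. Photosynthesis genes were lower by a median of -1.38, 6 lower and 1 higher (camera adjusted p = 0.0751). The photosynthesis list passed without root replicate 1 (0.0391, range 0.0234 to 0.842 over its camera alternatives), and the ribosomal list without cotyledon replicate 2 (0.0296), with no filter (0.0324) and with limited ratios kept (0.0262, range 0.0262 to 0.688). The root meristem list (3 higher, 1 lower, camera adjusted p = 0.447) and the auxin list (1 and 1, 0.671) did not pass. In all, 2616 genes had a higher and 2606 a lower response in cotyledon. With arrays centred on the median of all values these were 2462 and 1267, and 66.0% in place of 50.1% were higher. With arrays scaled to 1 median absolute value they were 2561 and 2984, with 46.2% higher.

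The contrast of petal with root was led by JAL22, which was at -2.45 ± 0.55 in root. UGT72E1 (AT3G50740), a UDP-glycosyltransferase gene, was at 3.26 ± 0.52 in petal and -2.66 ± 0.27 in root, and BCAT4 (AT3G19710), of methionine-derived glucosinolate synthesis, at 2.71 ± 0.82 and -2.91 ± 0.73. OSM34 was at 3.51 ± 0.66 in petal. SWEET1 fell to -2.11 ± 1.35 in petal, and SAG29 (AT5G13170), also a SWEET sugar transporter, was at -3.11 ± 1.43 in petal and 2.05 ± 0.78 in root. UGT85A3 (AT1G22380) was at -4.28 ± 1.35 in petal and 1.13 ± 2.79 (n = 3) in root, and RALFL25 at -0.03 ± 1.68 (n = 3) in root. The limma adjusted p of these 8 differences was 0.00274 or less, and that of UGT85A3 was lost with limited ratios kept (-3.58, 0.128, range 0.00117 to 0.128). LBD16 rose more in petal than in root, by 2.61 (adjusted p = 0.00145). Photosynthesis genes fell further in petal, 8 of 12 members over all genes and 9 adjusted over the list alone, by a median of -1.40 (camera adjusted p = 0.0175; adjusted p = 0.688 with an estimated correlation). This list call was lost with no dye term (0.0925) and with arrays scaled to 1 median absolute value (0.723), in a range from 0.00041 to 0.723, and 14 of the 35 splits of these 8 arrays gave at least 1 list. All 3 ribosomal genes rose more in petal (camera adjusted p = 0.0688), and their list passed without cotyledon replicate 2 (0.0362), with no filter (0.0324) and with limited ratios kept (0.0262, range 0.0262 to 0.688). The cell cycle list had 2 higher members over all genes and 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.675). The auxin list (2 higher, 1 lower, 0.675) and the root meristem list (2 and 2, 0.675) did not pass, and the latter had a median of 0.25 and a mean of -0.21. In all, 3237 genes had a higher and 2587 a lower response in petal. With centring on the median of all values these were 3913 and 1134, and 77.5% in place of 55.6% were higher. With arrays scaled to 1 median absolute value they were 2462 and 2469, with 49.9% higher.

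The contrast of petal with cotyledon asked where these organs differ in their change to callus. BCAT4 fell to -3.93 ± 0.40 in cotyledon against its rise in petal, and AOP3 was at -0.07 ± 0.48 in petal. UGT72E1 was at -1.81 ± 0.06 in cotyledon, and the organic cation transporter gene OCT5 (AT1G79410) at -2.67 ± 0.18 in cotyledon and 2.37 ± 0.37 in petal. SAG29 was at 2.34 ± 0.43 in cotyledon. UPB1, which rose in cotyledon and fell in petal, and the vacuolar processing enzyme gene BETA-VPE (AT1G62710), at 0.62 ± 1.71 in cotyledon and -4.33 ± 0.15 in petal, were lower in petal. CSLA01 was at 0.55 ± 2.76 (n = 3) in cotyledon. These 8 differences had a limma adjusted p of 0.0155 or less, and CSLA01 lost its call without cotyledon replicate 3 (-4.13, adjusted p = 0.0532), when arrays were scaled (-4.15, 0.0648) and with limited ratios kept (-3.74, 0.196), in a range from 0.00182 to 0.196. LBD16 did not differ detectably (-0.20, adjusted p = 0.772). Of the photosynthesis genes, LHCB4.3 was lower in petal by -3.19 (adjusted p = 2.05e-05) and 11 did not pass (camera adjusted p = 0.357). AUR1 and AUR2 were lower and MCM7 higher in petal (list camera adjusted p = 0.411), and the root meristem list (2 lower, 0.235) and the auxin list (1 higher, 1 lower, 0.921) did not pass, the latter with a median of 0.32 against a downward camera shift. The 3 ribosomal genes did not pass either way, with a median of 0.61 (camera adjusted p = 0.613). Of the smaller lists, the ARR16 ratio was lower in petal than in root by -3.32 and than in cotyledon by -3.78. The YAB3 ratio was lower in cotyledon (-2.80) and petal (-3.06) than in root, and the EXPA7 ratio was higher in both (2.00 and 1.97). The PHV ratio was lower in cotyledon (-1) and petal (-0.54) than in root and higher in petal than in cotyledon (0.46). Those of PDF1.2, RBE and EXPA18 did not differ detectably. In all, 2982 genes had a higher and 1818 a lower response in petal than in cotyledon. With centring on the median of all values these were 2657 and 1094, and 70.8% in place of 62.1% were higher.

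**Figure D4:**
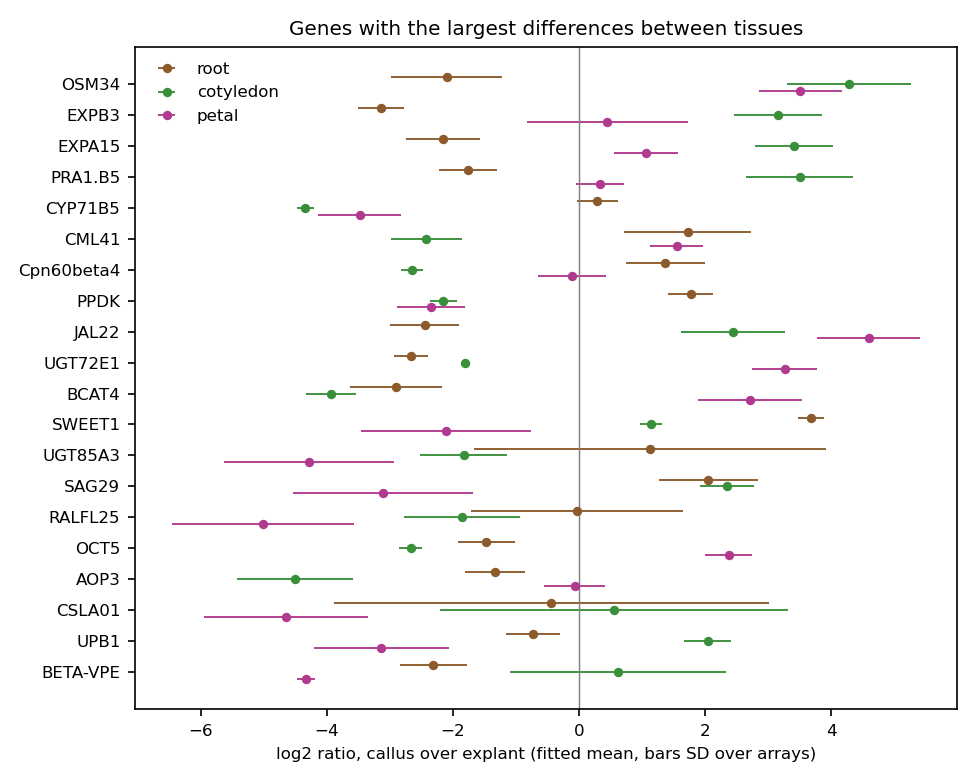
Fitted log2 ratios of callus over explant (x axis, points, with the SD over arrays as bars) in root, cotyledon and petal for the named genes with the largest differences between tissues (y axis). BCAT4 lies at 2.71 in petal and at -3.93 and -2.91 in cotyledon and root.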

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

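The tests on exchanged dye labels, limited ratios, centring and photosynthesis genes were chosen after the results were seen, while the splits of the arrays were set beforehand.

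Of 122 groups of 4 values looked at, 101 of them single genes, 6 had 1 value far from the other 3, where chance gives about 1 in 20, or 6.1. ATL43 stood at 3.06 on root replicate 2 against 2.53 to 2.59 on the others. On root replicate 3, tny was at -2.86 against -4.01 to -3.92, BZIP24 at -2.58 against -3.39 to -3.30, UPB1 at -0.09 against -1.03 to -0.88 and CYP71B34 at -2.20 against -2.90 to -2.85. ATLP-1 stood at 4.78 on cotyledon replicate 1 against 2.57 to 2.84.

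The response of 5222 genes differed between cotyledon and root, of 5824 between petal and root and of 4800 between petal and cotyledon, each tested as a contrast in limma. Cotyledon minus root was 6.39 for OSM34, 6.29 for EXPB3, 5.58 for EXPA15, 5.27 for PRA1.B5, -4.63 for CYP71B5, -4.14 for CML41, -4.03 for Cpn60beta4 and -3.92 for PPDK. Petal minus root was 7.04 for JAL22, 5.91 for UGT72E1, 5.63 for BCAT4, 5.61 for OSM34, -5.80 for SWEET1, -5.41 for UGT85A3, -5.15 for SAG29 and -4.98 for RALFL25. Petal minus cotyledon was 6.64 for BCAT4, 5.07 for UGT72E1, 5.05 for OCT5, 4.45 for AOP3, -5.45 for SAG29, -5.20 for CSLA01, -5.18 for UPB1 and -4.95 for BETA-VPE. The photosynthesis genes differed between petal and root by a median of -1.40 (camera adjusted p = 0.0175; adjusted p = 0.688 with an estimated correlation), a call also lost with no dye term (0.0925) and with arrays scaled (0.723). Of the 49 other named genes, 41 differed in at least 1 of these contrasts. Among all 9695 genes, 53.9% differed between cotyledon and root, 60.1% between petal and root and 49.5% between petal and cotyledon. Most of the named genes were picked for large ratios or low adjusted p, so 41 of 49 does not set them apart.

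Splitting the 8 arrays of a pair of tissues into other groups of 4 argued against chance as the source of all differences. It does not measure how many of the called genes are false. Every other split mixes the tissues, so their difference widens the spread and lowers the count. Of 35 splits, 1 gave as many genes for cotyledon and root (5222, highest other 6), for petal and root (5824, highest other 21) and for petal and cotyledon (4800, highest other 0). For the genes changed in all 3 tissues, 1 of 100 drawn ways of turning the ratios gave as many (3301, highest other 0). Turning ratios that differ from 0 widens the spread as well, so the same limit holds. Within a tissue the 8 ways of turning 4 ratios are too few for a share under 0.05. The count was 6092 in root (highest other 1), 6883 in cotyledon (highest other 4) and 7622 in petal (highest other 53), reached in 1 of 8 ways each. For lists these counts were 1 in root (highest other 2, reached in 6 of 8 ways), 2 in cotyledon (highest other 3, in 4 of 8) and 1 in petal (highest other 1, in 5 of 8). For the 1 list that differed between petal and root, 14 of 35 splits gave as many (highest other 2), so chance cannot be excluded.

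Limited values were outside the comparisons. At the lower limit on all 4 arrays of a tissue were 90 probes in petal, 55 of them with a gene, and 14 in cotyledon, where independent arrays would give 1.15 and 0.039, and in root there were 0. Callus carried each dye on 2 arrays per tissue, so a probe that only follows the dye would not be at the lower limit on all 4. In root, 1168 probes followed the dye to opposite limits. Weak probes could still reach a limit together, so the count for independent arrays assumes more than the arrays show. Whether these probes reflect transcript levels was not tested.

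On petal replicate 1, 5996 ratios were at the lower limit although callus carried Cy5, the dye with which limited root ratios lay at the upper limit. An exchanged dye label predicts that this array deviates against the dye effect of the other tissues, with a correlation under 0. Pearson's correlation, aligned to the label, was 0.15 (SD 0.11 over the other 11 arrays, 0.04 to 0.35 over all 12), but Spearman's was 0.09, within its SD of 0.12. The control spots had a median of -6.64 on this array, as on root replicate 2 and petal replicate 2 with callus in Cy3, whereas 11 of 12 photosynthesis genes were lower on both petal arrays with callus in Cy3 than on this array and petal replicate 3. An exchanged label, a weak callus channel, for which intensities were not analysed here, and a difference of this petal sample itself therefore stay open.

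More genes were higher than lower in each tissue. If the removal of limited ratios made this so, keeping them would take the share of higher genes to 50% or less. It was 64.2% in root, 54.1% in cotyledon and 44.6% in petal, and the petal value met this prediction. Limited petal ratios were mostly at the lower limit, 5996 on replicate 1 and 7022 on replicate 2. On both arrays the control spots had a median of -6.64. Keeping such ratios adds mostly lower calls, among 13510 genes in place of 9695, so the petal share cannot decide between this explanation and a true excess. Limited root ratios, however, were mostly at the upper limit with callus in Cy5 and at the lower with callus in Cy3. Kept, they point both ways and can hardly be called, so the root share decides nothing. In cotyledon limited ratios followed the dye in part, so the share argues only weakly against the explanation there. After centring on tested probes the shares were 52.2%, 52% and 51.7%, but centring itself pulls the share towards 50%, so the authors' centring and a true excess cannot be told apart. A real excess of induced genes in callus stays open and was not tested apart from this.

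Photosynthesis genes were lower in root callus, an organ not expected to be green. If signal shared by light-harvesting paralogs caused this, members outside that family would not be lower, but 8 of 8 were, which argues against it. Green tissue among the root explants would bring other cotyledon transcripts. The 228 other genes at -3 or less in cotyledon had a root median of -1.23 (quartiles -2.07 and -0.34), 141 of them lower and 14 higher, against -1.84 for the photosynthesis genes. Green tissue predicted a median at or under that of the photosynthesis genes, and this one lies above it but below the bound set for excluding green tissue. The value decides nothing, so green tissue and a callus response shared by both organs cannot be told apart.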

How the results depend on the processing

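Keeping limited ratios, centring on tested probes or on all values, and leaving out root replicate 1 and petal replicate 1 were chosen after seeing the data. Of the values of 129 results for named genes under the alternatives, 3288 kept direction and side of the threshold, 19 lost the threshold, 1 gained it and 1 reversed, namely AUR3 in root at -0.81 (adjusted p = 0.66, range 9.45e-06 to 0.66) with limited ratios kept. The construction shows the cause, as its 1 limited root value then entered. Of the values of 30 list results, 749 kept their side, 35 gained the threshold, 10 lost it and 1 reversed, the root meristem list in petal with fry (adjusted p = 0.016), which asks whether the genes move and not whether they differ from other genes. Of the values of 16 counts and correlations, 374 stayed within their bounds and 49 did not.

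With every probe on its own, 18169 were tested in place of 9695 genes, and the counts grew with that number to 11239 in root, 12971 in cotyledon, 14089 in petal, 9875 for cotyledon and root, 10817 for petal and root, 8903 for petal and cotyledon and 5910 in all 3 tissues. With a log2 ratio of at least 1 asked for as well, they were 2299, 3889, 4991, 3026, 3480, 2468 and 1083 in that order, as a stricter threshold gives. The other alternatives kept these 7 counts within 1.5 times.

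With no filter the correlation of root with cotyledon was 0.31 and with petal 0.37. With limited ratios kept it was 0.30 and 0.33, and 0.79 for cotyledon and petal. Leaving out 1 array gave 0.47 (without root replicate 2) to 0.54 for root and petal. The cause was not tested.

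The number of lists in root was 1, and 2 with each tissue fitted alone, 2 with no filter, 0 with an estimated correlation and 4 with fry. In cotyledon it was 2, and 1 with each tissue fitted alone, 1 on probes measured on all 12 arrays, 4 with no filter, 3 with limited ratios kept, 3 without cotyledon replicate 2, 1 without root replicate 1 and petal replicate 1, 0 with an estimated correlation and 5 with fry. In petal it was 1, and 2 with no filter, 2 with limited ratios kept, 0 with an estimated correlation and 5 with fry. Between cotyledon and root it was 0, and 2 with no filter, 2 with limited ratios kept, 1 with centring on all values, 1 without root replicate 1 and petal replicate 1, 3 with fry and 0 to 1 with 1 array left out. Between petal and root it was 1, and 0 with no dye term, 0 with arrays scaled, 2 with no filter, 2 with limited ratios kept, 0 with an estimated correlation, 3 with fry and 1 to 2 with 1 array left out. Between petal and cotyledon it was 0, and 2 with fry. Without a filter 6 lists and with limited ratios kept 8 were large enough to test. The cause was otherwise not tested.

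Other camera results that gained the threshold were the auxin list in root with each tissue fitted alone (0.0491), the cell cycle list in root with no filter (0.0455) and between cotyledon and root with no filter (0.0324) and limited ratios kept (0.0488), the root meristem list in cotyledon with no filter (0.05 after rounding), and photosynthesis between cotyledon and root with centring on all values (0.0234) and without root replicate 1 and petal replicate 1 (0.0369). Over their alternatives, the adjusted p of the photosynthesis list ran from 9.6e-07 to 0.378 in root, 6.92e-07 to 0.378 in cotyledon and 6.89e-08 to 0.378 in petal, and passed in 25 of 26 each, all but the estimated correlation, with fry left out as it asks another question. Centring on measured ratios moved the median of all genes in root from 0.18 to 0.07, and centring on all values moved it in petal from 0.18 to 0.60.

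Replicate numbers go with the dye. Of 12 pairs of the same number, 9 correlated over 0.1 before the dye term (-0.10 to 0.31) and 1 after it (-0.32 to 0.19). The dye term is shared by the tissues, so removing it lowers these correlations by itself, and the drop cannot exclude a pairing. The numbers were not taken to pair the arrays across tissues. With the replicate block in place of the dye term the counts were 5995 in root, 6825 in cotyledon, 7641 in petal and 3274 in all 3.

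Each tissue fitted alone gives no contrast, and neither the size threshold nor single probes gave a list test. Signal over background was not analysed here, so it is unknown which ratios rest on weak spots.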

Other observations

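All tests in this part were chosen after the data were seen. Gene families, formed by symbols that share their starting letters with at least 8 tested members, gave 24 families and 72 tests with camera over the 3 tissues, of which 6 passed. In petal callus 7 of 9 SWEET sugar transporters fell, with a median of -2.85 (camera adjusted p = 0.0246; adjusted p = 0.529 with an estimated correlation), among them SWEET4 at -4.78 and SWEET2 at -4.31. In cotyledon callus 7 fell and SWEET1 rose, with a median of -2.82, and the family did not pass (camera adjusted p = 0.0534), while centring on measured ratios (0.0345), centring on all values (0.00434) and scaling (0.0443) took it past the threshold and centring on tested probes did not (0.0859). In root callus 4 members fell and SWEET1 at 3.68 and SWEET14 at 1.26 rose, with a median of -0.83 (camera adjusted p = 0.28). SAG29, also a SWEET gene, is outside this group by its symbol.

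The other 5 tests that passed were of families lower in root callus, with no test of whether root differs from the other tissues. The CYP genes had a median of -1.42 in cotyledon (8 lower, 2 higher, camera adjusted p = 0.0754) and -1.71 in petal (8 lower, 2 higher, 0.0644), and the GSTU genes went both ways in cotyledon (4 lower, 3 higher, 0.721) and petal (4 lower, 2 higher, 0.738). In cotyledon the PRA genes had 3 lower and 3 higher members (0.721), the TBL genes 8 and 4 (0.477) and the UGT genes 15 and 6 (0.141), and in petal these were 7 and 1 (0.18), 6 and 3 (0.252) and 14 and 12 (0.503). Of 8 GSTU glutathione transferases 7 fell, with a median of -0.95 (camera adjusted p = 0.0246; adjusted p = 0.529 with an estimated correlation), GSTU23 to -2.49 and GSTU22 to -2.03. Of 14 CYP genes 7 fell and 1 rose, with a median of -0.56 (0.0246; adjusted p = 0.529 with an estimated correlation). The gene that rose was CYP71 (AT3G44600) at 0.84, a cyclophilin and not a cytochrome P450. Of 11 PRA genes 7 fell (median -0.50, 0.0246; adjusted p = 0.624 with an estimated correlation), of 14 TBL genes 7 fell (median -0.43, 0.026; adjusted p = 0.529 with an estimated correlation), and of 32 UGT glycosyltransferases 16 fell and 5 rose (median -0.30, 0.0246; adjusted p = 0.453 with an estimated correlation). The 6 medians kept their sign and their calls under the 4 other centrings and scalings, and differences of families between tissues were not tested.

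The 12 control spots with a value, which were left out of every test, had a median at the limit of -6.64 on root replicate 2 and petal replicates 1 and 2 and of 4.08 on root replicate 1. On the other arrays the medians were -0.04 and 0.00 in root replicates 3 and 4, -0.68, -3.46, 0.38 and -3.18 in cotyledon replicates 1 to 4, and -0.24 and -0.28 in petal replicates 3 and 4.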
